A study of Staphylococcus aureus with 40 samples.

How the data were processed

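Messenger RNA and small RNA were sequenced from Staphylococcus aureus JKD6008 and JKD6009 at 2 h and 6 h, without antibiotic or after 10 min with 1 of 4 antibiotics at 0.5 times the minimum inhibitory concentration, giving 20 libraries per preparation and 40 in all. Per the series design text, Illumina reads were set against the complete JKD6008 genome, and the text names limma and non-negative matrix factorization for the statistics. Per the submitters' processing notes, edgeR was used, with no version and no role given. The aligner, the counting program and whether counting was strand-specific are not given in the sources used here. The deposited tables hold a raw read count per annotated gene (2767 genes, 1243 with a symbol) or per listed small RNA locus (410 loci) for every library, with no normalization, as their whole numbers and differing column totals show. Per the file headers, the authors also deposited a normalizing multiplier per library, a ratio that scales counts between libraries, which served only in an alternative. A further column, headed per the file headers as listing features on the same fragment, names neighbouring features and was used only to say where reads may be shared. Gene symbols, products and small RNA annotations are those of the deposited tables, and a reference gene table of another strain was not used. No column of the count tables that holds a sample was left out.

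Libraries were grouped by strain, time and antibiotic from their labels, and the comparisons, tests, gene lists, alternatives and naming rule were chosen before the data were examined, except those said below to be added later. Counts were analysed in R 4.3.3 with edgeR 4.0.16, with TMM scaling, its default filter on low counts and the quasi-likelihood test, for each preparation apart. The model held the strain-by-time cell (4 levels, the block within which exposed and unexposed libraries were matched) and the antibiotic (5 conditions), with 12 residual degrees of freedom, or 8 with antibiotic interaction terms. Contrasts gave each antibiotic against none, the cell-wall-active against the ribosome-targeting class, JKD6008 against JKD6009, 6 h against 2 h and the strain-by-time term. Antibiotic interactions with strain and with time were F tests over 4 coefficients. All tests were two-sided, p-values were adjusted by Benjamini-Hochberg over the 2300 genes or 355 loci tested, and an adjusted p of 0.05 was the threshold. Fold changes are fitted values with their standard errors, CPM values (counts scaled to library size) come with the SD over libraries, and per-library log2 values used a prior count of 2.

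Named genes followed a rule. For each messenger RNA comparison of an antibiotic, strain or time it took the 8 largest rises and 8 largest falls among genes past the threshold with at least 20 mean counts over the 20 libraries and the same sign in every matched pair, 4 for an antibiotic and 10 for strain or time. For small RNA and for the class contrast it took 5 and 5, for an interaction the 5 lowest p, and where none passed the 4 lowest p as values. Per gene list it allowed up to 4 members with the lowest p. The grouping of the 4 ribosomal antisense loci was made after their values were seen. Of the lists fixed beforehand, 28 for messenger RNA and 2 for small RNA with at least 3 members were tested with camera in limma 3.58.1 at a preset correlation of 0.01, with an estimated correlation and fry as alternatives. A fold against a group with no counts is given as a bound against a floor of 3 counts over the group, and a group with 1 to 3 counts as a pooled ratio with a 95% exact counting interval. Overlap of calls between antibiotics was set against independent lists, simulated unchanged groups and unexposed libraries split between both antibiotics.

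Alternatives were median-of-ratios scaling, the deposited multipliers as library sizes, no filter on low counts, DESeq2 1.42.0, limma-voom, a model with strain, time and antibiotic as separate terms in place of the cell, no strain-by-time block (the factor compared as the single term), only the 8 libraries compared, and each library left out in turn. The tests without the 5 libraries of JKD6008 at 2 h, without the 4 ribosomal antisense loci, of the strains at each time and of the times in each strain, and of an antibiotic interaction with JKD6008 at 2 h were added, with the slopes of the antibiotic responses, the spread of the growth test, the test of locus lengths and the splits of matched pairs, whole antibiotics and cells, after the data were seen. The edgeR procedure was tested on simulated counts for 2300 genes with 200 changed. For linezolid it recovered 65% of those changed by 1 on the log2 scale and 93% of those changed by 2, with 4 false among 162 calls. For strain it recovered 89.3% and 100%, with 8 false among 197. For 355 small RNA loci with 71 changed, it recovered 2.5% and 3.23% for linezolid with 0 false among 2 calls, and 12.9% and 82.5% for strain with 0 false among 37. No library was a copy of another: the lowest chi-square per degree of freedom between any pair was 3.47 in messenger RNA and 34.4 in small RNA. The closest messenger RNA pair was ceftobiprole and linezolid in JKD6008 at 2 h. They lay closer to each other than to the unexposed library of that strain and time (6.53 and 6.17).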

Results

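RNA was sequenced from Staphylococcus aureus JKD6008, a vancomycin-intermediate strain, and JKD6009, a vancomycin-susceptible strain, each grown in Mueller Hinton broth and sampled at 2 h or 6 h. Cultures were exposed for 10 min to 0.5 times the minimum inhibitory concentration of ceftobiprole, linezolid, tigecycline or vancomycin, or were left unexposed. Every culture condition gave 1 library of messenger RNA and 1 library of small RNA, so that each preparation had 20 libraries, with 4 per antibiotic condition, 10 per strain and 10 per time. Each combination had a single library and the labels do not say that cultures were separate, so the p-values rest on the residual of an additive model, and that residual can hold technical spread alone. Intervals and detection floors cover counting error only.

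Messenger RNA libraries held 335102 to 443654 counts in the unexposed group and 361146 to 428891 with vancomycin. The totals were 586915 to 847784 with ceftobiprole, 479882 to 2218591 with tigecycline and 768126 to 1921742 with linezolid. Of 2767 listed genes, 2511 to 2698 had counts in a library and 2300 were tested. The 5 libraries of JKD6008 at 2 h stood apart from the other 15 on the first principal component of log2 CPM (counts scaled to the TMM library size), whatever the antibiotic. After the model terms, the common biological coefficient of variation of the 20 libraries was 0.238.

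**Figure D1:**
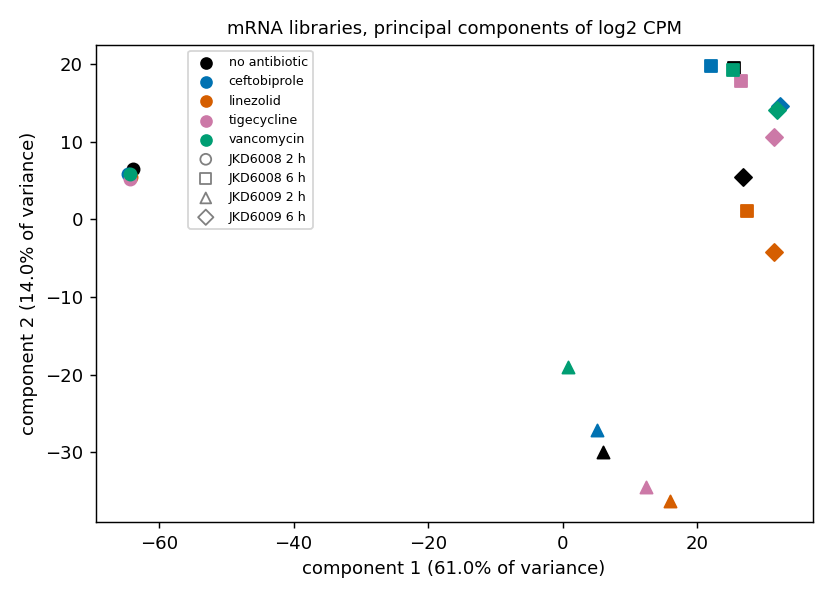
Principal components of the 20 messenger RNA libraries, from log2 CPM, with component 1 (61.0% of the variance) on the horizontal axis and component 2 (14.0%) on the vertical axis. Each point is a library, its colour gives the antibiotic and its marker the strain and time. The 5 libraries of JKD6008 at 2 h lie between -64.6 and -63.8 on component 1 and the others between 0.87 and 32.3.

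In the unexposed small RNA libraries 4 loci took most of the counts, and their share differed between antibiotic conditions. JKD6008sRNA101, JKD6008sRNA117, JKD6008sRNA322 and JKD6008sRNA339, annotated as antisense to ribosomal RNA genes, together took 98.5% ± 0.516 of the counts in the unexposed libraries (SD, n = 4). Their share was 40.5% ± 17.4 with vancomycin, 6.95% ± 2.54 with ceftobiprole, 3.75% ± 0.904 with linezolid and 0.348% ± 0.219 with tigecycline (SD, n = 4 each). The 4 loci had near-equal counts and are all annotated opposite ribosomal RNA genes, and whether their reads can be told apart was not checked by sequence. They were grouped by their values and are called the 4 ribosomal antisense loci below. Other loci with such an annotation, JKD6008sRNA116 and JKD6008sRNA338, are not in the group and rose with ceftobiprole. The sources do not say that counting was strand-specific, so a locus called antisense here may also hold reads from the opposite strand. Total counts were 1564125 to 2958881 per unexposed library, 37114 to 337505 with vancomycin, 58341 to 112327 with ceftobiprole, 65893 to 130180 with linezolid and 68509 to 181892 with tigecycline. Outside the 4 loci, the unexposed libraries held 17697 to 44687 counts and the exposed libraries 26587 to 180865. Of 410 listed loci, 355 were tested, and the common biological coefficient of variation was 0.702.

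**Figure D2:**
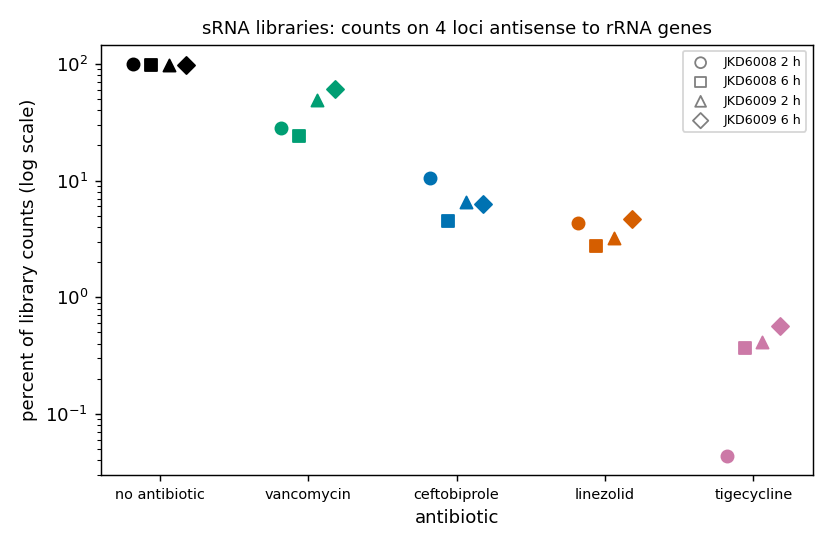
Percent of the counts of each small RNA library (vertical log axis) that fell on JKD6008sRNA101, JKD6008sRNA117, JKD6008sRNA322 and JKD6008sRNA339, 4 of the loci annotated as antisense to ribosomal RNA genes. Antibiotic conditions are on the horizontal axis, with 4 libraries per condition as points. The unexposed libraries sit between 98.0% and 99.2%, and the tigecycline libraries between 0.0438% and 0.565%.

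Ceftobiprole, a cephalosporin that binds penicillin-binding proteins, was compared with no exposure to describe the early transcriptional response to a cell-wall-active drug. The beta-lactamase regulator gene blaR1 rose by 1.87 ± 0.28 on the log2 scale (SE, edgeR adjusted p = 0.00112), from 60.3 ± 6.87 to 232 ± 124 CPM (SD, n = 4). The biofilm operon repressor gene icaR rose by 1.74 ± 0.26 (edgeR adjusted p = 0.00112), and the cold-shock protein gene cspC rose from 787 ± 473 to 2013 ± 1139 CPM (SD, n = 4), a log2 change of 1.45 ± 0.27. The call of cspC ended without the 5 libraries of JKD6008 at 2 h (edgeR adjusted p = 0.0549). Genes gatC, ylmG, SAA6008_02450 and SAA6008_01018 rose by 1.5, 1.38, 1.47 and 1.33. Among the falls were SAA6008_02345, a cell envelope-related attenuator gene, at -0.97 ± 0.15 (edgeR adjusted p = 0.00112), the heat shock-like RNA-binding gene SAA6008_00511 at -0.99, and the shikimate kinase gene aroK at -2.0 ± 0.39. Every gene named had the same sign in 4 of 4 matched pairs unless a smaller number is given.

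Of the 13 measured antibiotic resistance and efflux genes, 4 rose with ceftobiprole and none fell, with the same 4 when adjusted over the list alone. They were blaR1, mecR1 (1.0), and, with the sign shared by 3 of 4 pairs, the beta-lactamase gene blaZ (3.19 ± 0.63, edgeR adjusted p = 0.0088) and the penicillin-binding protein 2a gene mecA (1.92 ± 0.38). The list ranked above other genes in camera (adjusted p = 0.00161; adjusted p = 0.471 with an estimated correlation). Among 56 ribosomal protein genes, 2 rose, rpsT (1.16) and rpmB (0.89), with 2 when adjusted over the list alone and a camera adjusted p = 0.00633 (adjusted p = 0.958 with an estimated correlation). In the VraSR cell wall stress list, 11 of 11 genes did not pass in edgeR with ceftobiprole, nor when adjusted over the list alone, and the median log2 change was -0.01 (camera adjusted p = 0.848). In all, 63 genes passed in edgeR, 37 higher and 26 lower, but 106 with DESeq2 (58 and 48), 327 in edgeR with only the 8 libraries compared (167 and 160) and 48 with no filter on low counts (34 and 14). The count fell to 35, 26, 29 and 22 without the unexposed library of JKD6008 at 2 h, JKD6008 at 6 h, JKD6009 at 2 h and JKD6009 at 6 h. It was 31, 27 and 25 without the ceftobiprole library of JKD6008 at 2 h, JKD6008 at 6 h and JKD6009 at 6 h. Without 1 library the call of aroK ended (adjusted p = 0.0603 in edgeR without unexposed JKD6008 at 6 h and 0.0524 without unexposed JKD6009 at 6 h). At their highest adjusted p in edgeR, so did those of stbD (log2 change -1.21; 0.0747 without ceftobiprole JKD6008 at 6 h), paaD (-1.19; 0.084 without the same library) and SAA6008_00894 (-0.98; 0.0542 without unexposed JKD6008 at 6 h), and that of SAA6008_01767 (-1.03; 0.0669 without unexposed JKD6008 at 2 h). Without unexposed JKD6008 at 6 h, SAA6008_01063 (-1.01) and SAA6008_01222 (1.31) reached 0.17 and 0.121. Without the 5 libraries of JKD6008 at 2 h, the calls of SAA6008_01222, stbD, SAA6008_01767 and SAA6008_00894 ended (edgeR adjusted p = 0.151, 0.065, 0.165 and 0.0948).

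Vancomycin, a glycopeptide that binds peptidoglycan precursors, was compared with no exposure for the same question. The ribosomal protein gene rpsF rose from 614 ± 68.0 to 1961 ± 397 CPM (SD, n = 4), a log2 change of 1.64 ± 0.31 (edgeR adjusted p = 0.00859). The stress regulator gene spxA rose by 1.46 ± 0.27 (edgeR adjusted p = 0.00734) and the phage amidase gene SAA6008_01834 by 2.07 ± 0.36 (edgeR adjusted p = 0.00515). The lowest adjusted p belonged to SAA6008_00378, of unknown function, at -2.43 ± 0.30, and SAA6008_02345 and the transposase gene SAA6008_00894 changed by -1.10 and -1.34. The glycolytic phosphoglycerate kinase gene pgk had a log2 change of -1.5 ± 0.35 (edgeR adjusted p = 0.0357).

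Of 9 glycolysis genes, 1 fell with vancomycin, pgk, and 4 when adjusted over the list alone (camera adjusted p = 0.00418; adjusted p = 0.986 with an estimated correlation). Of 14 fermentation and nitrate respiration genes, 14 did not pass in edgeR over all genes, while 1 was higher and 4 were lower adjusted over the list alone. Camera gave this list an adjusted p = 0.00418 (adjusted p = 0.986 with an estimated correlation). In the VraSR list, 11 of 11 genes did not pass with vancomycin in edgeR, nor when adjusted over the list alone, with a median log2 change of 0.02, a mean of -0.01 and a camera adjusted p = 0.942. Outside these lists, the virulence regulator gene saeR rose by 1.28 and the elongation factor gene efp by 0.81, and the surface protein genes clfB and sdrC fell, with log2 changes of -0.88 and -1.14. In all, 50 genes passed in edgeR, 26 higher and 24 lower, out of 387 with an unadjusted p under 0.05, but 128 passed with DESeq2 (62 and 66). The count fell to 18, 18 and 29 without the unexposed library of JKD6008 at 6 h, JKD6009 at 2 h and JKD6009 at 6 h. It was 33 and 29 without the vancomycin library of JKD6008 at 6 h and JKD6009 at 6 h.

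Most single genes named for vancomycin lost their call in edgeR when some 1 library was left out, and 5 did not: SAA6008_01834, spxA, SAA6008_00378, SAA6008_00894 and SAA6008_02345. Without unexposed JKD6009 at 2 h the adjusted p was 0.0519 for rpsF, 0.0655 for SAA6008_01067 (1.46), 0.111 for SAA6008_00724 (1.54), 0.108 for SAA6008_01594 (1.53) and 0.12 for SAA6008_00879 (-1.09). Without unexposed JKD6008 at 6 h it was 0.0834 for SAA6008_00882 (2.36), 0.082 for xseB (1.63) and 0.112 for SAA6008_01961 (-1.48). For pgk it was 0.118 without unexposed JKD6009 at 6 h, for SAA6008_00814 (-1.34) 0.0847 without vancomycin JKD6008 at 2 h, and for the pyridoxine synthesis gene SAA6008_00526 (-1.01) 0.122 without vancomycin JKD6009 at 2 h. Without the 5 libraries of JKD6008 at 2 h, SAA6008_00724, SAA6008_01594, SAA6008_01961, SAA6008_00814, SAA6008_00879 and SAA6008_00526 were not called (edgeR adjusted p = 0.0615, 0.0641, 0.138, 0.0699, 0.0615 and 0.127). With only the 8 libraries compared, pgk and SAA6008_01961 were not called (edgeR adjusted p = 0.0702 and 0.0793).

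Linezolid, which binds the ribosome and blocks the start of protein synthesis, was compared with no exposure to describe the response to a ribosome-targeting drug. The ribosomal protein gene rpsF rose from 614 ± 68.0 to 4162 ± 2135 CPM (SD, n = 4), a log2 change of 2.61 ± 0.32 (edgeR adjusted p = 0.000123). The initiation factor gene infC rose by 2.32 ± 0.49 (edgeR adjusted p = 0.00389), the accessory regulator gene sarR by 2.35 ± 0.36, the ferredoxin gene fer by 2.27 and the pyrimidine operon regulator gene pyrR by 2.22 ± 0.57. Genes SAA6008_00712, SAA6008_00882 and SAA6008_02605 rose by 3.0, 2.18 and 2.16. The shikimate kinase gene aroK fell from 248 ± 167 to 28.1 ± 9.42 CPM (SD, n = 4), a log2 change of -2.94 ± 0.42 (edgeR adjusted p = 0.000356). Other falls were accB_1 (-2.58) and SAA6008_01579 (-2.27), the amylase gene malA (-2.06), and 3 adjacent transporter-region genes, SAA6008_01964 (-2.54), SAA6008_01965 (-2.08) and SAA6008_01966 (-2.04), for which the deposited table lists reads on the same fragments.

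Ribosomal protein genes rose together with linezolid: 51 of 56 were higher and 1 was lower, or 53 and 1 adjusted over the list alone, with a median log2 change of 1.41. Examples were rpsM (1.89), rpsT (1.83) and rpsD (1.67), and camera gave an adjusted p = 2.33e-28 (adjusted p = 0.626 with an estimated correlation). Of 11 translation factor genes 7 rose, 8 adjusted over the list alone, among them tsf (1.43) and infA (1.41), with a camera adjusted p = 0.000599 (adjusted p = 0.626 with an estimated correlation). Aminoacyl-tRNA synthetase genes went the other way: 11 of 20 fell, or 12 with 1 higher adjusted over the list alone, with serS at -1.82, hisS at -1.77, tyrS at -1.61 and alaS at -1.0. Camera gave this list an adjusted p = 2.47e-05 (adjusted p = 0.626 with an estimated correlation). Of 17 purine synthesis genes 10 rose, including purA (2.06), purE (1.63) and purH (1.32), with 10 higher and 1 lower adjusted over the list alone and a camera adjusted p = 0.00167 (adjusted p = 0.909 with an estimated correlation). Of 15 tricarboxylic acid cycle genes 5 fell, 8 adjusted over the list alone, such as acsA (-1.43), odhB (-1.27) and fumC (-0.94), with a camera adjusted p = 0.000405 (adjusted p = 0.909 with an estimated correlation).

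Cell wall genes moved in both directions with linezolid. Of 16 measured WalKR and autolysis genes 5 rose, among them the autolysin gene atl (1.52), ssaA_1 (1.79) and isaA (1.43), with 5 higher and 1 lower adjusted over the list alone and a camera adjusted p = 0.111. In the VraSR list of 11, murZ (0.72), pbp2 (0.79) and fmt (0.63) rose and 2 fell, including the response regulator gene vraR (-1.08), with 3 and 2 adjusted over the list alone. Its median and mean log2 changes, -0.01 and -0.03, differed in sign from the direction of its camera test (adjusted p = 0.855). Of the 13 resistance and efflux genes 3 rose, the methyltransferase genes ermA (0.99) and ermA_1 (0.98) and, in 3 of 4 pairs, tetM (1.72), with 3 adjusted over the list alone and a camera adjusted p = 0.0313 (adjusted p = 0.628 with an estimated correlation). In all, 557 genes passed in edgeR, 310 higher and 247 lower, but 292 with only the 8 libraries compared (182 and 110). The count fell to 306, 328 and 354 without the unexposed library of JKD6008 at 6 h, JKD6009 at 2 h and JKD6009 at 6 h. It was 292 and 308 without the linezolid library of JKD6008 at 6 h and JKD6009 at 6 h. The fructose phosphate kinase gene pfkB, at -2.04 ± 0.70 (edgeR adjusted p = 0.0435), moved to -0.42 (edgeR adjusted p = 0.266) without unexposed JKD6009 at 6 h, and was not called by limma-voom (adjusted p = 0.141). With only the 8 libraries compared, SAA6008_00882 was not called (edgeR adjusted p = 0.0557).

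Tigecycline, a tetracycline derivative, was compared with no exposure for the same question. The ribosomal protection gene tetM rose from 389 ± 227 to 1984 ± 1035 CPM (SD, n = 4), a log2 change of 2.55 ± 0.55 (edgeR adjusted p = 0.00698). The MarR-family regulator gene SAA6008_02558 rose by 2.76 ± 0.52 (edgeR adjusted p = 0.00335), infC by 2.51 ± 0.50 (edgeR adjusted p = 0.00426) and the adenylosuccinate synthetase gene purA by 2.47 ± 0.49. The regulator gene frmR and its neighbour SAA6008_02124, a putative copper chaperone gene, rose by 2.39 and 2.33, with reads listed on the same fragments, and SAA6008_00724 and SAA6008_01281 rose by 2.48 and 2.20. SAA6008_00378, of unknown function, fell from 121 ± 59.8 to 17.5 ± 5.56 CPM (SD, n = 4), a log2 change of -2.74 ± 0.28 (edgeR adjusted p = 2.62e-05). Other falls were aroK (-2.71 ± 0.41), SAA6008_01966 (-1.86), SAA6008_00555 (-1.63), SAA6008_00814 (-1.52) and the ribonuclease III gene SAA6008_00537 (-1.51).

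Of 56 ribosomal protein genes, 27 rose with tigecycline, or 42 higher and 1 lower adjusted over the list alone, including rpmA (2.12), rpsR (1.78) and rpmF (1.43). Camera gave an adjusted p = 5.79e-15 (adjusted p = 0.804 with an estimated correlation). Translation factor genes rose in 4 of 11 cases, among them tsf (1.16), rbfA (0.80) and efp (0.55), with 4 adjusted over the list alone and a camera adjusted p = 0.0373 (adjusted p = 0.804 with an estimated correlation). Of 20 aminoacyl-tRNA synthetase genes, gltX rose (0.55) and 5 fell, including pheT (-1.31), tyrS (-1.25) and ileS (-1.05), with 1 and 9 adjusted over the list alone and a camera adjusted p = 0.000654 (adjusted p = 0.804 with an estimated correlation). Of 9 glycolysis genes 4 fell and 5 did so adjusted over the list alone, including pgk (-1.18) and pgi (-1.14), with a camera adjusted p = 0.00248 (adjusted p = 0.804 with an estimated correlation). Of 13 resistance and efflux genes 5 rose, tetM, mepR (1.46), ermA (0.97) and ermA_1 (0.99) among them, with 5 adjusted over the list alone and a camera adjusted p = 0.00418 (adjusted p = 0.804 with an estimated correlation).

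In all, 303 genes passed in edgeR with tigecycline, 176 higher and 127 lower, but 104 with only the 8 libraries compared (65 and 39). The count fell to 131 and 194 without the unexposed library of JKD6009 at 2 h and at 6 h, and to 155 and 181 without the tigecycline library of JKD6009 at 2 h and at 6 h. The glyceraldehyde phosphate dehydrogenase gene gap, at -1.5 ± 0.45 (edgeR adjusted p = 0.0349), moved to -0.80 (edgeR adjusted p = 0.182) without unexposed JKD6009 at 6 h. Without unexposed JKD6009 at 2 h the calls of frmR (edgeR adjusted p = 0.0529) and SAA6008_01965 (-1.33; edgeR adjusted p = 0.0996) ended. With only the 8 libraries compared, frmR and gap were not called (edgeR adjusted p = 0.0794 and 0.125).

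**Figure D3:**
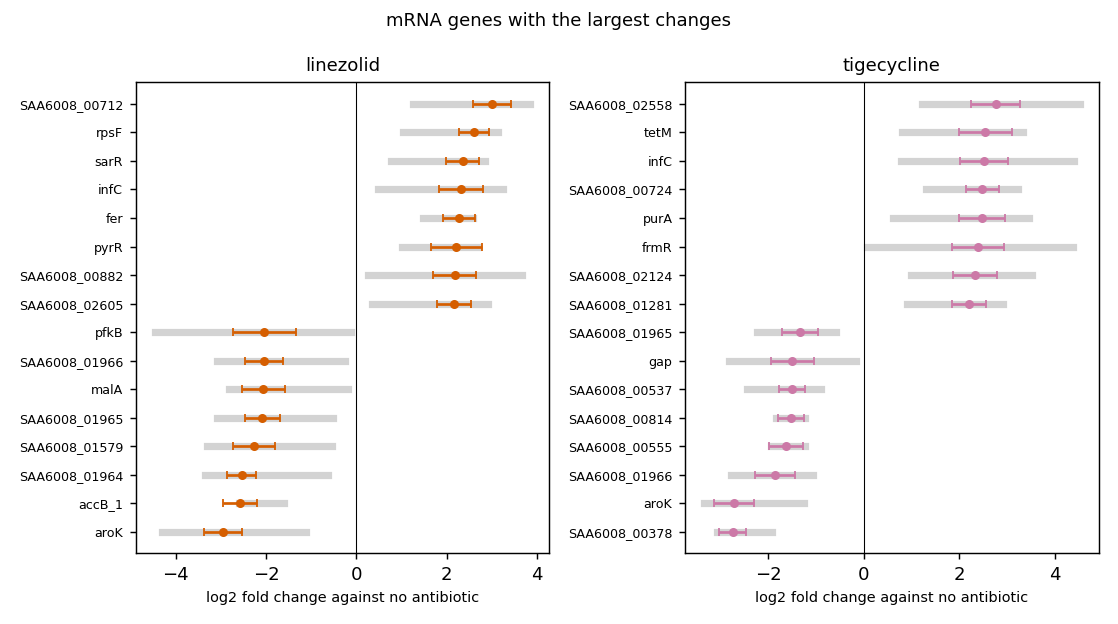
Fitted log2 fold change (horizontal axis) of the genes named for linezolid and for tigecycline (vertical axis), as points with bars of 1 standard error; each gray bar spans the 4 matched pairs of exposed and unexposed libraries. With linezolid, rpsF is at 2.61 and aroK at -2.94, and with tigecycline tetM is at 2.55 and SAA6008_00378 at -2.74.

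The antibiotic calls rested on comparing each exposed library with the unexposed library of the same strain and time. With strain and time as separate terms in place of that strain-by-time block, edgeR called 3 genes for ceftobiprole, 110 for linezolid, 55 for tigecycline and 2 for vancomycin. With no block and no other term than the antibiotic, it called 0, 8, 6 and 1. Without the 5 libraries of JKD6008 at 2 h, a choice made after the data were seen, the counts were 29 for ceftobiprole, 700 for linezolid, 370 for tigecycline and 24 for vancomycin.

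Pairs of antibiotics called some genes in common. Linezolid and tigecycline shared 127 genes in the same direction and 8 in opposite directions, where independent lists of those sizes would share 37.4. Simulated unchanged groups with common controls shared 0, as they give hardly any calls. With the 4 unexposed libraries split between both antibiotics, the mean shared number was 9. Each antibiotic then had fewer unexposed libraries, which can also lower its number of calls, so 9 cannot be set against 37.4. The same limit holds for the split controls of the other pairs, and of small RNA below. The covariance of the fold changes exceeded the simulated one by 0.178, and their correlation was 0.542 against 0.571 simulated. Ceftobiprole and linezolid shared 40 genes in the same direction and 0 in opposite ones (independent lists 7.78, simulated 0, split controls 4, covariance excess 0.0659). Tigecycline and vancomycin shared 27 and 0 (independent lists 3.31, simulated 0, split controls 3.67, covariance excess 0.0649). Ceftobiprole and vancomycin, both cell-wall-active, shared 8 and 0 (independent lists 0.69, simulated 0, split controls 1.17, covariance excess 0.0276). For ceftobiprole with tigecycline the numbers were 19 and 2 (independent lists 4.27, simulated 0, split controls 2.17, covariance excess 0.019), and for linezolid with vancomycin 18 and 2 (independent lists 6.08, simulated 0, split controls 2.83, covariance excess 0.0048). For these 5 pairs, in the same order, the correlations were 0.382, 0.418, 0.391, 0.292 and 0.178 against 0.572, 0.524, 0.525, 0.564 and 0.538 simulated. All 6 lay below the values that common unexposed libraries gave in unchanged groups. Changes particular to 1 antibiotic also lower a correlation, so it cannot decide whether responses were shared. The covariance exceeded the mean of 20 simulations in all 6 pairs, by as little as 0.0048. The spread of the simulated covariances was not recorded, so a small excess cannot decide it either.

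The cell-wall-active drugs, ceftobiprole and vancomycin, were set directly against the ribosome-targeting drugs, linezolid and tigecycline, with 8 libraries in each class. The genes tetM (-2.45 ± 0.40, edgeR adjusted p = 0.000945), purA (-2.17), infC (-2.11), frmR (-1.98) and SAA6008_02124 (-1.96) were lower with the cell-wall-active drugs. Transporter-region genes SAA6008_01964 (2.17 ± 0.21), SAA6008_01966 (1.82) and SAA6008_01963 (1.73), and the aldehyde dehydrogenase gene SAA6008_00145 (1.73), were higher. The amino acid permease gene SAA6008_02479 (1.66) was also higher, but its call ended in edgeR without linezolid JKD6008 at 6 h (adjusted p = 0.0556) or linezolid JKD6009 at 6 h (adjusted p = 0.0586), and in DESeq2.

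Of 56 ribosomal protein genes, 2 were higher and 44 lower with the cell-wall-active drugs, or 2 and 49 adjusted over the list alone (camera adjusted p = 1.49e-21; adjusted p = 0.737 with an estimated correlation). Translation factor genes were lower in 8 of 11 cases, and in 8 adjusted over the list alone (camera adjusted p = 3.83e-05; adjusted p = 0.737 with an estimated correlation). Aminoacyl-tRNA synthetase genes were higher in 14 of 20 cases, or 16 higher and 3 lower adjusted over the list alone (camera adjusted p = 9.88e-05; adjusted p = 0.737 with an estimated correlation). Of 8 pyrimidine genes 4 were lower and 5 adjusted over the list alone (camera adjusted p = 0.00995). Of 15 genes of the tricarboxylic acid cycle and gluconeogenesis, 4 were higher and 6 adjusted over the list alone (camera adjusted p = 0.00207). Both lists had an adjusted p = 0.916 with an estimated correlation in camera. In all, 667 genes passed in edgeR, 323 higher and 344 lower, and 430 passed without tigecycline JKD6009 at 2 h. With strain and time as separate terms 175 passed (53 higher and 122 lower), and with no block and no term but the class 6.

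Whether an antibiotic acted differently in the 2 strains or at the 2 times was tested by interaction terms. For strain, edgeR called 0 of 2300 genes (113 with an unadjusted p under 0.05; DESeq2 called 1 and limma-voom 0). The lowest adjusted p in edgeR, 0.825, was shared by frmR, SAA6008_02491, SAA6008_01960 and SAA6008_02594. For time, edgeR called 59 genes, and DESeq2 and limma-voom 99 and 46, while 8 of 100 random groupings of the libraries gave as many in edgeR, the real grouping included. The succinate dehydrogenase gene sdhB, the citrate synthase-family gene citZ, the phenol-soluble modulin genes SAA6008_01127 and SAA6008_01128, and the transporter gene SAA6008_02547 had the lowest adjusted p in edgeR, 0.00217 each.

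JKD6008 was compared with JKD6009 to describe how the vancomycin-intermediate strain differed from the susceptible one. The phosphate-binding protein gene pstS was higher in JKD6008 by 6.43 ± 0.27, with 4046 ± 4186 against 20.9 ± 33.2 CPM (SD, n = 10 each), as were pstC, pstA, pstB and phoU by 5.62, 5.38, 4.72 and 4.53. The alkaline phosphatase gene phoA was higher by 4.34 and the transglycosylase gene sceD by 4.76 ± 0.26 (edgeR adjusted p = 8.79e-11). Among the lower genes were the phenol-soluble modulin genes SAA6008_01127 (-5.33 ± 0.45, edgeR adjusted p = 1.62e-08), SAA6008_01128 (-4.05) and SAA6008_09900 (-3.34), the alpha-hemolysin gene hlY (-3.88 ± 0.30) and the coagulase gene coa (-3.03 ± 0.26). SAA6008_00586 was higher by 4.28, and pdxS, SAA6008_02416 and SAA6008_01776 differed by -2.87, -3.20 and -3.10. These genes had the same sign in 10 of 10 matched pairs.

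Of the 11 VraSR cell wall stress genes, 9 were higher and 2 lower in JKD6008, including prsA (2.41), sgtB (2.01), vraS (1.54) and msrR (1.45) among the higher ones, with 9 and 2 adjusted over the list alone (camera adjusted p = 0.000258; adjusted p = 0.0565 with an estimated correlation). Of 7 genes for GraRS, teichoic acid D-alanylation and MprF, 5 were higher, such as fmtC (1.63), dltD (1.11) and dltB (1.0), with 5 adjusted over the list alone (camera adjusted p = 0.00372; adjusted p = 0.279 with an estimated correlation). In the agr and toxin list of 10, 1 was higher and 5 were lower, among them agrB (-2.47), agrA (-2.46), hld (-2.28) and agrD (-2.27), with 1 and 5 adjusted over the list alone (camera adjusted p = 0.000258; adjusted p = 0.171 with an estimated correlation). Chaperone and Clp protease genes were higher in 10 of 12 cases, 10 adjusted over the list alone (camera adjusted p = 1.33e-05; adjusted p = 0.0565 with an estimated correlation). However, clpB (2.00) and hrcA (1.86) were higher in only 5 of 10 pairs. Of 17 purine genes 14 were lower, 15 adjusted over the list alone (camera adjusted p = 6.5e-07; adjusted p = 0.325 with an estimated correlation). Of 9 ATP synthase genes 8 were lower, 9 adjusted over the list alone (camera adjusted p = 0.0026; adjusted p = 0.567 with an estimated correlation). Oxidative stress genes were higher in 9 of 10 cases, including dps (1.85) and ahpC (1.71), with 9 adjusted over the list alone (camera adjusted p = 0.000136; adjusted p = 0.247 with an estimated correlation).

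In all, 1504 genes passed between the strains in edgeR, 773 higher and 731 lower in JKD6008, and 355 of them averaged at least 20 counts and had the same sign in 10 of 10 pairs. The 5 libraries of JKD6008 at 2 h stood apart from the rest, and without them 224 genes passed. Of the 16 genes named, 15 could then be tested and 8 kept their call. Those tested and not called were pstA, pstB, phoU, pdxS, SAA6008_00586, SAA6008_01776 and SAA6008_02416.

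The strain difference was also tested at each time, a choice made after the data were seen. At 2 h, pstS reached 7959 ± 1061 CPM in JKD6008 against 4.10 ± 1.35 in JKD6009 (SD, n = 5 each), a log2 difference of 10.99 ± 0.44 (edgeR adjusted p = 9.62e-13). SAA6008_02246, annotated as an MHC class II analog protein, differed by 8.76, the peptidase gene SAA6008_00181 by 6.97 and phoA by 6.94. The xanthine phosphoribosyltransferase gene xprT (-6.16) and pdxS (-5.04) were lower in JKD6008. Counts were near the floor in JKD6008 at 2 h for several lower genes: hlY had 2 counts over 5 libraries there, and JKD6009 exceeded it by a pooled ratio of 51.1 (95% counting interval 14.0 to 424.7). SAA6008_01127, also with 2 counts, was exceeded by a pooled ratio of 378 (95% counting interval 104 to 3125). At 6 h the glycine betaine synthesis genes gbsA (4.39 ± 0.33, edgeR adjusted p = 1.14e-07) and betA (4.30 ± 0.30, edgeR adjusted p = 6.07e-08) and the choline transporter gene cudT (3.07 ± 0.24) were higher in JKD6008. So were sceD (3.27), pstS (1.87 ± 0.31) and pstC (1.69). The alpha-hemolysin gene hlY (-2.39) and the phenol-soluble modulin alpha genes SAA6008_09903 (-2.17), SAA6008_09901 (-2.16), SAA6008_09902 (-2.14) and SAA6008_09900 (-2.03) were lower at 6 h, as was the aureusimine synthetase gene ausA (-2.02). The 7 genes for GraRS, D-alanylation and MprF included 5 that were higher at 6 h, 5 adjusted over the list alone (camera adjusted p = 4.7e-06; adjusted p = 0.127 with an estimated correlation). Of the 11 VraSR genes 2 were higher at 6 h (camera adjusted p = 0.0245; adjusted p = 0.245 with an estimated correlation), of the 10 agr and toxin genes 1 was higher and 5 lower (camera adjusted p = 0.0151; adjusted p = 0.613 with an estimated correlation), with the same numbers adjusted over each list alone. Of 17 purine genes 4 were lower at 6 h, 7 adjusted over the list alone (camera adjusted p = 0.00404; adjusted p = 0.776 with an estimated correlation). Of 10 oxidative stress genes 1 was higher, 3 adjusted over the list alone (camera adjusted p = 0.108), and 9 of 9 ATP synthase genes did not pass at 6 h, over all genes or over the list alone (camera adjusted p = 0.136). In all, edgeR called 1671 genes at 2 h, 853 higher and 818 lower, and 235 at 6 h, 125 higher and 110 lower.

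Later growth was described by comparing 6 h with 2 h. The lipase gene lip rose from 158 ± 150 to 7470 ± 4880 CPM (SD, n = 10 each), a log2 change of 5.83 ± 0.42 (edgeR adjusted p = 1.08e-09). The gene hlY rose by 5.53 and the phenol-soluble modulin genes SAA6008_01127 and SAA6008_09900 by 6.07 ± 0.45 and 5.45. The cell wall recycling gene murQ rose by 6.02 ± 0.36 (edgeR adjusted p = 9.34e-11), with its neighbour SAA6008_00169 (5.78) and the transport genes tauB (5.64) and SAA6008_00151 (5.51). Falls included SAA6008_00714 (-6.34), SAA6008_00716 (-5.97) and pfkB (-5.76), neighbours for which reads are listed on the same fragments. The glyceraldehyde phosphate dehydrogenase gene gap (-4.21 ± 0.31), SAA6008_00786 (-4.25), SAA6008_00586 (-5.79), SAA6008_00181 (-4.87) and the co-chaperonin gene groES (-4.19 ± 0.18, edgeR adjusted p = 1.44e-12) also fell. These genes had the same sign in 10 of 10 matched pairs.

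All 12 chaperone and Clp protease genes fell from 2 h to 6 h, with a median log2 change of -2.38 and with clpB at -3.68, ctsR at -3.53 and hrcA at -2.67. All 12 also fell when adjusted over the list alone (camera adjusted p = 2.4e-12, and 0.0157 with an estimated correlation). These values average the strains. Most genes of this list fell more in JKD6008 than in JKD6009, with strain-by-time values of -4.60 for clpB and -4.25 for hrcA. All 9 glycolysis genes fell, such as pgk (-3.88), tpi (-3.57) and eno (-2.26), with 9 adjusted over the list alone (camera adjusted p = 4.47e-05; adjusted p = 0.255 with an estimated correlation). All 15 tricarboxylic acid cycle and gluconeogenesis genes rose, among them gapB (4.19), pckA (3.56) and odhB (2.92), with 15 adjusted over the list alone (camera adjusted p = 4.94e-06; adjusted p = 0.336 with an estimated correlation). Of 17 purine genes 16 rose and 1 fell, with 16 and 1 adjusted over the list alone (camera adjusted p = 4.53e-06; adjusted p = 0.294 with an estimated correlation). In the agr and toxin list 9 of 10 rose and 10 adjusted over the list alone, including hld (4.44), agrD (2.11) and agrA (2.04) (camera adjusted p = 3.03e-05; adjusted p = 0.149 with an estimated correlation). The arginine deiminase genes arcB (4.68), arcD (4.56) and arcA (4.30) rose. In all, 1660 genes passed in edgeR, 822 higher and 838 lower at 6 h, 449 of them with at least 20 mean counts and the same sign in 10 of 10 pairs. Without the 5 libraries of JKD6008 at 2 h, and so in JKD6009 alone, 964 passed. With no strain-by-time block and no term but the factor compared, 1105 passed for time (412 higher and 693 lower) and 734 for strain (491 and 243).

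The change over time differed between JKD6008 and JKD6009 for many genes, as tested by the strain-by-time term. In edgeR 1358 genes passed, 692 positive and 666 negative, where a positive value means that JKD6008 rose more or fell less from 2 h to 6 h. The collagen adhesin gene cna (4.46 ± 0.19, edgeR adjusted p = 1.47e-11) was positive, and the heat shock repressor gene hrcA (-4.25 ± 0.22), the chaperone gene clpB (-4.60 ± 0.24), SAA6008_02246 (-9.30) and SAA6008_00833 (-6.18) were negative, each with an edgeR adjusted p = 1.32e-10. Of 12 chaperone and Clp protease genes, 9 were negative, 9 adjusted over the list alone (camera adjusted p = 6.44e-10; adjusted p = 0.0147 with an estimated correlation). At 2 h 11 of these 12 were higher in JKD6008, 11 adjusted over the list alone (camera adjusted p = 1.37e-07; adjusted p = 0.0298 with an estimated correlation). At 6 h groEL alone passed in edgeR, lower in JKD6008 (-0.63), with 1 adjusted over the list alone (camera adjusted p = 0.213). Within JKD6008, a comparison chosen after the data were seen, 1737 genes passed over time, among them arcA (6.66), lip (6.92) and groES (-6.84), and in JKD6009 958, among them murP (5.76), murQ (5.65), the manganese transporter genes mntA (4.83) and mntC (4.79), the gluconate repressor gene gntR (-3.82) and pgm (-3.09).

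Among small RNA loci, the 4 ribosomal antisense loci showed the largest falls in edgeR with ceftobiprole, linezolid and tigecycline. Small RNA folds and CPM values are relative to the bulk of the loci after TMM scaling. This scaling gave the unexposed libraries effective sizes of 49781 to 100728, far below their total counts. The falls of the 4 loci are therefore larger than those of their share of the total counts. JKD6008sRNA101 had log2 changes of -10.11 ± 0.90 with ceftobiprole, -11.04 ± 0.93 with linezolid and -13.91 ± 1.03 with tigecycline (edgeR adjusted p = 8.55e-12 for tigecycline), and JKD6008sRNA117, JKD6008sRNA322 and JKD6008sRNA339 lay between -10.05 and -14.03. Some loci were gained: with ceftobiprole JKD6008sRNA116, antisense to a ribosomal RNA gene, rose by 8.16 ± 0.96, JKD6008sRNA404 by 7.66, and JKD6008sRNA217, antisense to the ribosomal protein gene rpsB, by 6.76 ± 1.16, while JKD6008sRNA241 changed by -9.21. JKD6008sRNA338, antisense to a ribosomal RNA gene, and JKD6008sRNA213, antisense to pyrF, rose by 4.88 and 4.30. JKD6008sRNA128, antisense to the elongation factor gene tuf, had 0 counts over the 4 unexposed libraries and was at least 84.9-fold higher with linezolid, 11.4-fold with tigecycline and 48.4-fold with vancomycin, against a floor of 3 counts over the group. Every locus named here had the same sign in 4 of 4 pairs.

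With linezolid, JKD6008sRNA121 and JKD6008sRNA113, the latter antisense to lysS, were at least 118-fold and 50.7-fold higher than the same floor. The call of JKD6008sRNA121 ended in DESeq2 (adjusted p = 0.194). JKD6008sRNA72, antisense to the alkyl hydroperoxide reductase gene ahpF, rose by 9.09 ± 1.07, JKD6008sRNA127, antisense to the elongation factor gene fus, rose by 8.09 and JKD6008sRNA242, antisense to rpsA, changed by -7.43. With tigecycline, JKD6008sRNA407, antisense to lip, rose by 7.94 ± 1.13, JKD6008sRNA366 by 5.60 and JKD6008sRNA116 by 5.02. JKD6008sRNA144, antisense to rimL, had 1 count over the unexposed libraries and a pooled ratio of 173 (95% counting interval 31.0 to 6851), and JKD6008sRNA105 had 1 count with tigecycline against 860 without exposure. With only the 8 libraries compared, JKD6008sRNA128 was not called for tigecycline (edgeR adjusted p = 0.132). With vancomycin, JKD6008sRNA342 rose from 706 ± 811 to 37138 ± 16420 CPM (SD, n = 4), a log2 change of 6.20 ± 0.80 (edgeR adjusted p = 4.71e-07), and JKD6008sRNA366 and JKD6008sRNA407 rose by 5.37 and 5.09. JKD6008sRNA124, antisense to rplK, with 1 count over the unexposed libraries, had a pooled ratio of 85.6 (95% counting interval 15.2 to 3395). JKD6008sRNA105 and JKD6008sRNA148 had 0 counts with vancomycin and were at least 864-fold and 147-fold lower, and JKD6008sRNA241, JKD6008sRNA242 and JKD6008sRNA126 changed by -7.33, -7.47 and -6.84.

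In all, edgeR called 36 loci for ceftobiprole (12 higher and 24 lower, but 44 and 33 with DESeq2, 38 and 36 with only the 8 libraries compared, and 35 and 31 without the 5 libraries of JKD6008 at 2 h), 52 for linezolid (31 and 21), 30 for tigecycline (13 and 17, but 31 and 19 without tigecycline JKD6008 at 2 h, and 5 and 14 with only the 8 libraries compared) and 44 for vancomycin (22 and 22, but 36 and 32 with DESeq2). The median locus shifted by 0.27, 0.28, 0.58 and 0.29 on the log2 scale, and by 0.56, 0.44, 0.64 and 0.45 with median-of-ratios scaling, so that small changes relative to the other loci cannot be signed. Without the linezolid library of JKD6009 at 6 h the linezolid count was 29 (14 higher, 15 lower), without unexposed JKD6008 at 6 h the vancomycin count was 27 (12 and 15; and 29 with no strain-by-time block and no term but the antibiotic), and without tigecycline JKD6008 at 2 h the tigecycline count was 50. In simulated data the linezolid comparison recovered 3.23% of loci changed by 2 on the log2 scale, so a locus not called here may still have changed by several-fold. Shared calls in the same direction numbered 20 for ceftobiprole with vancomycin (opposite 1, independent lists 2.23, simulated 0, split controls 13.5, covariance excess 2.99) and 19 for tigecycline with vancomycin (1, 1.86, 0, 13.2 and 3.34, in that order). They were 18 for ceftobiprole with tigecycline (1, 1.59, 0.05, 14.5 and 3.83). They numbered 17 for linezolid with tigecycline (1, 2.14, 0, 10 and 2.69), 15 for ceftobiprole with linezolid (3, 2.47, 0, 10.7 and 2.43) and 15 for linezolid with vancomycin (5, 3.22, 0, 11 and 1.66). In the same order of the 6 pairs, the correlations of the fold changes were 0.687, 0.710, 0.747, 0.533, 0.520 and 0.407, against 0.547, 0.547, 0.553, 0.563, 0.563 and 0.552 simulated. The shared calls, covariances and correlations include the 4 ribosomal antisense loci, which were called for every antibiotic. Outside these 4 loci, 32, 48, 26 and 40 loci were called for ceftobiprole, linezolid, tigecycline and vancomycin. The overlap was not computed without the 4 loci, so how far it rests on them stays open.

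Between drug classes, JKD6008sRNA338 was 7.46 ± 0.74 higher on the log2 scale with the cell-wall-active drugs (edgeR adjusted p = 1.55e-08), and the 4 ribosomal antisense loci were 4.24 to 4.31 higher. For these 4 loci the drugs of a class were not alike. Their mean share of the counts was 6.95% with ceftobiprole and 3.75% with linezolid, but 40.5% with vancomycin and 0.348% with tigecycline. JKD6008sRNA10 and JKD6008sRNA197 were lower (-4.74 and -4.43). JKD6008sRNA148, JKD6008sRNA105 and JKD6008sRNA72 also passed as lower, but had at most 3 counts over the libraries of an antibiotic, so no fold is given. With each library left out in turn, 2 of 160 calls of the loci named for this contrast ended in edgeR. In all, 49 loci passed in edgeR, 19 higher and 30 lower, but 80 with DESeq2 (35 and 45). Vancomycin and tigecycline set against ceftobiprole and linezolid gave 51 loci in edgeR, so the number called is not particular to the drug classes. Interaction terms of the antibiotic with strain and with time called 0 loci in edgeR, with 4 and 3 loci at an unadjusted p under 0.05 and lowest adjusted p = 0.999 and 0.995, and DESeq2 and limma-voom also called 0.

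Between the strains, JKD6008sRNA131, annotated by similarity to the catalogued small RNA Teg47, was higher in JKD6008 by 4.55 ± 0.56 (edgeR adjusted p = 1.23e-06) in 10 of 10 pairs. It was the single locus called at 6 h (3.64 ± 0.77, edgeR adjusted p = 0.0178; not called by limma-voom). JKD6008sRNA317, annotated in the 3′ untranslated region of hld, was lower (-2.83 ± 0.35), as were JKD6008sRNA69 (-2.27) and JKD6008sRNA23 (-1.70). In all, 41 loci passed in edgeR, 24 higher and 17 lower, of which 8 had the same sign in 10 of 10 pairs, and 76 passed with DESeq2 (38 and 38). The count and the balance moved when 1 library was left out: 5 higher and 13 lower (18 in all) without unexposed JKD6008 at 6 h, 8 and 15 (23) without unexposed JKD6009 at 2 h, and 13 and 13 (26) without ceftobiprole JKD6009 at 2 h. Without the unexposed, tigecycline and vancomycin libraries of JKD6009 at 6 h, they were 11 and 15 (26), 9 and 13 (22), and 8 and 13 (21). Without unexposed JKD6008 at 6 h JKD6008sRNA306 (1.83), JKD6008sRNA221 (1.58), JKD6008sRNA407 (-2.05) and JKD6008sRNA128 (-1.69) were no longer called (adjusted p = 0.0728, 0.0999, 0.0629 and 0.0552 in edgeR), and 2 loci passed without the 5 libraries of JKD6008 at 2 h, where the comparison is at 6 h alone. Of the 8 named loci, 6 were then not called, among them JKD6008sRNA317, JKD6008sRNA69 and JKD6008sRNA23 (edgeR adjusted p = 0.0627, 0.502 and 0.0627). With all libraries, limma-voom did not call JKD6008sRNA407 and JKD6008sRNA128 (adjusted p = 0.107 and 0.159).

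From 2 h to 6 h, JKD6008sRNA317 rose by 4.23 ± 0.38 (edgeR adjusted p = 1.19e-09), beside the rise of hld itself (4.44), and JKD6008sRNA28 (4.26), JKD6008sRNA356 (Teg24 by similarity, 4.07), JKD6008sRNA69 (3.22) and JKD6008sRNA31 (Teg93 by similarity, 2.63) rose. JKD6008sRNA131 fell (-3.75 ± 0.55), as did JKD6008sRNA380 (-2.72), JKD6008sRNA146 (-2.19), JKD6008sRNA134 (-2.17) and JKD6008sRNA275 (-2.13), the last 4 of which were not called without the 5 libraries of JKD6008 at 2 h. In all, 45 loci passed in edgeR, 23 higher and 22 lower, or 32 and 18 with median-of-ratios scaling and 44 and 27 with DESeq2. Without those 5 libraries 23 passed, 20 higher and 3 lower. The strain-by-time term called 22 loci (58 with DESeq2), among them JKD6008sRNA133 (4.40), JKD6008sRNA36 (5.33), JKD6008sRNA318 (4.76), JKD6008sRNA317 (3.48) and JKD6008sRNA256 (-3.55). At 2 h 57 loci differed between the strains, with JKD6008sRNA387 (7.55), JKD6008sRNA90 (6.22) and JKD6008sRNA260 (6.12) higher and JKD6008sRNA318 (-5.35) and JKD6008sRNA36 (-5.11) lower in JKD6008.

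Of 96 loci annotated as Teg transcripts, 12 were higher and 4 lower in JKD6008, or 13 and 4 adjusted over the list alone (camera adjusted p = 0.0152; adjusted p = 0.533 with an estimated correlation). For the strain-by-time term 5 were positive and 4 negative, 6 and 4 adjusted over the list alone. Of 17 riboswitch and T-box loci 1 passed, 1 adjusted over the list alone (camera adjusted p = 0.00566 for each list; adjusted p = 0.398 with an estimated correlation). Over time 12 Teg loci rose and 12 fell, 12 and 12 adjusted over the list alone (camera adjusted p = 0.333). Ceftobiprole gave 3 higher and 2 lower Teg loci, linezolid 8 and 2, tigecycline 3 and 1, and vancomycin 7 and 3. Adjusted over the list alone, these were 2 and 1, 8 and 1, 1 and 0, and 7 and 2, with camera adjusted p = 0.733, 0.889, 0.995 and 0.872. Over the 8 comparisons planned for lists, 224 tests were made in messenger RNA and 16 in small RNA. Of these, 61 and 3 passed in camera with the preset correlation. With an estimated correlation 2 passed: the chaperone list over time and in the strain-by-time term.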

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

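The tests of a weaker response of JKD6008 at 2 h, including its slopes and interaction, and of the 4 ribosomal antisense loci were chosen only after the results were seen. So were the spread over single pairs in the growth test and the splits of matched pairs, whole antibiotics and cells. Groups of 4 values were tested for 1 library far from the other 3. The values were library totals, shares of the 4 ribosomal antisense loci, and matched log2 differences of genes and loci named for an antibiotic. Of 119 groups 9 were flagged, all of them matched log2 differences. The usual rate of about 1 in 20 groups cannot be applied, since named features were chosen by these differences and some share a signal. Of the 9, 8 lay in JKD6008 at 2 h. For linezolid, rpsF was at 1.03 there against 2.94 to 3.13 in the others, and for ceftobiprole SAA6008_01767 was at -1.5 against -0.82 to -0.71. With tigecycline, JKD6008sRNA144 was at 2.64 there against 5.36 to 5.65, and the ribosomal antisense loci JKD6008sRNA339, JKD6008sRNA117, JKD6008sRNA322 and JKD6008sRNA101, with near-equal counts, were at -17.06, -17.055, -16.43 and -15.88 against -13.65 to -13.35. This tigecycline library had counts on 276 loci, the fewest of the small RNA libraries, and 30 counts on the 4 ribosomal antisense loci. With vancomycin, JKD6008sRNA366 was at 2.46 in JKD6008 at 2 h against 5.70 to 6.29, and SAA6008_01594 was at 3.01 in JKD6009 at 2 h against 0.85 to 1.15 elsewhere. In size, the flagged differences of JKD6008 at 2 h were smaller than elsewhere for some features and larger for others.

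Strain differences changed with time for 1358 genes, among them cna (4.46), hrcA (-4.25), clpB (-4.60), SAA6008_02246 (-9.30) and SAA6008_00833 (-6.18), and for 22 small RNA loci, among them JKD6008sRNA133 (4.40), JKD6008sRNA256 (-3.55), JKD6008sRNA317 (3.48), JKD6008sRNA318 (4.76) and JKD6008sRNA36 (5.33), where the values are log2 differences of differences. The antibiotic-by-time term called 59 genes in edgeR, a number that other splits of the libraries also reached (8 of 100), with the lowest adjusted p, 0.00217, for sdhB, SAA6008_01127, citZ, SAA6008_02547 and SAA6008_01128.

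The first pattern is that the JKD6008 libraries at 2 h stood apart in messenger RNA, and without them the strain calls went from 1504 to 224. Lower depth is argued against, since thinning every library to 335102 counts kept a share of at least 0.883 of the 1671 strain calls at 2 h over 10 draws. Exchanged strain labels at 2 h are argued against too, but weakly: over the 5 antibiotic conditions at least 65.1% of the 235 genes called at 6 h had the same sign at 2 h. The 5 conditions are not separate checks, and whatever set the JKD6008 libraries at 2 h apart could also set these signs. An earlier point of growth in JKD6008 could not be decided: the lower correlation across genes, between the 2 h strain difference and the change over time in JKD6009, was 0.0327, and over 20 single pairs it ran from -0.092 to 0.265, with 15 above 0. A difference between the strains that holds at 2 h stays open as the biological explanation, and with 1 culture condition per cell a difference in how that culture was grown cannot be told apart from it.

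The second pattern is the size of the antibiotic responses. Deeper libraries are argued against as the reason that linezolid gave more calls than vancomycin, since after thinning to equal totals the ratio of the counts was at least 7.32, and the scaling factors of the linezolid libraries (0.707 to 0.973) lay below those of vancomycin (0.991 to 1.33). The slope of the response of JKD6008 at 2 h, on the response called without it, was 0.143 for linezolid (lowest other cell 0.653), 0.272 for tigecycline (0.594), 0.342 for ceftobiprole (0.737, with no slope for JKD6008 at 6 h) and 0.674 for vancomycin (0.776). For the 50 genes with the lowest p these were 0.206 (0.49), 0.346 (0.638), 0.443 (0.758) and 0.647 (0.656), so that for vancomycin the cells were close. In both sets of genes, the slope of JKD6008 at 2 h was the lowest among the cells with a slope for every antibiotic. Each slope rests on 1 exposed and 1 unexposed library, and the slopes of a cell share the unexposed one. The interaction of antibiotic with JKD6008 at 2 h gave 0 genes in edgeR (172 with an unadjusted p under 0.05), 20 in DESeq2 and 0 in limma-voom. In small RNA it gave 16 loci in edgeR, 48 in DESeq2 and 5 in limma-voom. A test with no call cannot exclude a weaker response. Whether the lower slopes hold beyond these single libraries, and why they were lower, stays open.

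The third pattern is that the 4 ribosomal antisense loci took most counts of the unexposed small RNA libraries. Whether their share shaped the other small RNA calls stays open: at least 95.8% of the other antibiotic calls were kept without them, but leaving them out moved the scaling of no library by more than 1.24 times and cannot restore the depth that they took. A difference in how the unexposed libraries were prepared cannot be told apart from an effect of the antibiotics, because each of the 4 unexposed libraries had at least 98.0% of its counts on these loci and the labels give no batch. An effect of exposure itself stays open and untested.

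Splits of the libraries were counted for each comparison, with the real split included. For an antibiotic all 35 splits of the 8 libraries were made, and the 8 that part all 4 matched pairs are too few for a share under 0.05. In messenger RNA the splits with as many calls, the real number and the highest other were 1 of 35, 63 and 4 for ceftobiprole, 1 of 35, 557 and 295 for linezolid, 1 of 35, 303 and 1 for tigecycline, and 1 of 35, 50 and 0 for vancomycin. In small RNA they were 1 of 35, 36 and 0 for ceftobiprole, 1 of 35, 52 and 0 for linezolid, 1 of 35, 30 and 28 for tigecycline, and 1 of 35, 44 and 0 for vancomycin. Among the 8 splits the highest other was the same, except 0 for tigecycline in messenger RNA. Of these 8, the split with 295 for linezolid and that with 28 for tigecycline in small RNA exchanged only the pair of JKD6008 at 2 h.

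For class, strain, time and strain-by-time, 100 splits took single libraries as independent, although libraries share an antibiotic or a growth condition. In messenger RNA the real number and the highest other were 423 and 152 for class, 1217 and 2 for strain, 1382 and 1040 for time, and 1358 and 1083 for strain-by-time, each with 1 of 100 splits as high. In small RNA they were 49 and 24, 20 and 9, 34 and 26, and 22 and 10, again with 1 of 100 each. These class splits had the cell and the class alone in the model, and those of strain and time had strain, time and antibiotic as separate terms. Whole antibiotics can be paired in 3 ways and the 4 cells split in 3 ways, too few for a share under 0.05. The highest other pairing of antibiotics, vancomycin and tigecycline against ceftobiprole and linezolid, called 327 genes against 423 and 51 small RNA loci against 49.

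For the antibiotic-by-time term in messenger RNA 8 of 100 splits gave as many calls (real 59, highest other 64), so chance cannot be excluded. Where the real number was 0, every split gives as many and the count says nothing about chance: antibiotic-by-strain (100 of 100 in messenger RNA, highest other 74, and 100 of 100 in small RNA, highest other 0) and antibiotic-by-time in small RNA (100 of 100, highest other 0).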

How the results depend on the processing

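Tests without the 5 libraries of JKD6008 at 2 h, without the 4 ribosomal antisense loci, at single times or in single strains, and of the antibiotic interaction with JKD6008 at 2 h were chosen only after the results were seen. No planned count moved by more than 1.5 times under median-of-ratios scaling, the deposited multipliers, no filter or limma-voom, though the balance of higher and lower calls shifted in some. For ceftobiprole it was 34 and 14 with no filter, against 37 and 26, and for tigecycline 206 and 103 with the deposited multipliers and 202 and 97 with no filter, against 176 and 127. No named gene changed direction under any setting. Of the added tests, the small RNA strain count at 6 h, 1 locus, became 2 with median-of-ratios scaling and 0 with limma-voom. With DESeq2 the messenger RNA counts became 106 for ceftobiprole, 128 for vancomycin, 1 for the antibiotic-by-strain and 99 for the antibiotic-by-time interaction. The small RNA counts became 77 for ceftobiprole, 68 for vancomycin, 80 for class, 76 for strain, 71 for time and 58 for strain-by-time. They were 96 and 8 for strain at 2 h and at 6 h, and 77 and 36 for time in JKD6008 and in JKD6009. The added interaction of antibiotic with JKD6008 at 2 h gave 20 genes and 48 loci with DESeq2, 5 loci with limma-voom and 9 loci without the 4 ribosomal antisense loci. With strain and time as separate terms beside the antibiotic, in place of their cell, messenger RNA counts became 3 for ceftobiprole, 110 for linezolid, 55 for tigecycline, 2 for vancomycin and 175 for class, and the small RNA strain count 20. With no replicate block, that is with the factor compared as the single term, messenger RNA counts became 0 for ceftobiprole, 8 for linezolid, 6 for tigecycline, 1 for vancomycin, 6 for class, 734 for strain and 1105 for time. Small RNA counts without this block became 29 for vancomycin, 3 for strain and 26 for time. With only the 8 libraries compared, messenger RNA counts became 327 for ceftobiprole, 292 for linezolid and 104 for tigecycline, and small RNA counts 74 for ceftobiprole and 19 for tigecycline. Without the 5 libraries of JKD6008 at 2 h, messenger RNA counts became 29 for ceftobiprole, 24 for vancomycin, 224 for strain (then at 6 h alone) and 964 for time (then in JKD6009 alone). Small RNA counts became 66 for ceftobiprole, 50 for tigecycline, 2 for strain and 23 for time. Of 64 gene list calls, 2 held with an estimated correlation. Leaving out 1 library gave, in messenger RNA, 22 (without unexposed JKD6009 at 6 h) to 61 for ceftobiprole and 292 (without linezolid JKD6008 at 6 h) to 768 for linezolid. It gave 131 (without unexposed JKD6009 at 2 h) to 370 for tigecycline, 18 (without unexposed JKD6008 at 6 h, as without unexposed JKD6009 at 2 h) to 36 for vancomycin and 430 (without tigecycline JKD6009 at 2 h) to 870 for class. In small RNA it gave 29 (without linezolid JKD6009 at 6 h) to 54 for linezolid, 21 to 50 (without tigecycline JKD6008 at 2 h) for tigecycline, 27 (without unexposed JKD6008 at 6 h) to 46 for vancomycin and 18 (without the same library) to 44 for strain. The cause was not tested for any of these. Of the named values, 301 of 302 kept their side of the threshold under median-of-ratios scaling, 300 of 302 with the deposited multipliers, 300 of 302 with no filter, 296 of 300 with DESeq2 and 294 of 302 with limma-voom. So did 97 of 104 with only the 8 libraries, 136 of 174 with strain and time as separate terms, 96 of 174 with no block, 144 of 172 without JKD6008 at 2 h, 97 of 97 without the 4 ribosomal antisense loci and 2031 of 2152 with 1 library left out. The unexposed small RNA libraries held 17697 to 44687 counts outside the 4 ribosomal antisense loci, so loci with low counts there could be missed, and how far depth limited the calls was not tested.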

Other observations

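The test of locus lengths was chosen only after the results were seen. Of 8 surface adhesin genes, 3 were higher and 3 lower in JKD6008 in edgeR, with the same numbers adjusted over the list alone (camera adjusted p = 0.926; adjusted p = 0.949 with an estimated correlation). The gene eap was higher (log2 difference 3.40), and clfB (-1.97) and sdrE (-1.51) were lower. Of 12 branched-chain amino acid synthesis genes 9 were higher and 1 was lower in JKD6008. These strain numbers include the 5 libraries of JKD6008 at 2 h, without which all strain calls went from 1504 to 224. Of 5 capsule synthesis genes, 3 were higher with the cell-wall-active than with the ribosome-targeting drugs (camera adjusted p = 0.0264; adjusted p = 0.916 with an estimated correlation). With ceftobiprole, the alkyl hydroperoxide reductase gene ahpC rose by 1.03, as 1 of 10 oxidative stress genes.

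Small RNA loci were set beside their host or target genes over time, across loci, which are not independent replicates. Loci annotated in an untranslated region followed the gene (Pearson r = 0.868, Spearman rho = 0.719, over 42 of 53 annotated loci, permutation p = 1e-05, the smallest that 100000 permutations can give, and 1e-05 adjusted over the 2 relations). Without the 2 loci whose host gene changed farthest from the median gene, r was 0.796. This is consistent with reads from the host transcript being counted at these loci. For antisense loci the hypothesis was that they mirror their target, moving against it. The correlation was positive instead (r = 0.551, rho = 0.231, 122 of 161 loci, permutation p = 1e-05, adjusted 1e-05). It fell to 0.319 without the 2 loci whose target gene changed farthest from the median gene.

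Loci called for an antibiotic but not for strain or time were short, with a median length of 104.5 nt over 74 loci, 70.3% of them antisense. The 53 loci called for strain or time alone had a median of 190 nt with 9.43% antisense (permutation p = 0.00149 for the difference in median length), the 15 called for both 113 nt, and all 355 tested 184 nt with 48.2% antisense. This was a pattern noticed in the data, and whether RNA degradation or preparation could account for it was not tested.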
